A study of Mus musculus with 2 samples.

How the data were processed

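Droplet single-cell RNA sequencing of mouse lung cells was analysed in 2 libraries, 1 from adult and 1 from neonatal animals. Per the labels' protocols, lungs were digested with collagenase and DNase, leukocytes were enriched on a Percoll gradient, and viable cells low in or positive for CD45 and low in a cocktail of lineage markers were sorted as reporter-negative and reporter-positive cells at a ratio of 2 to 1. The neonatal gate alone also excluded CD8. Libraries were made with the 10x Chromium 3′ kit of v2 chemistry, per the labels' protocols. Each deposited file holds whole-number UMI counts per gene and barcode with no normalization, per the file headers and the values themselves. Cell Ranger 2.0.1, Seurat 2.1.0, R 3.4.2 and the genome build mm10 are named in the submitters' processing notes. Their roles, the annotation and the rule by which barcodes were called cells are not given in the sources used here. The lowest total of any barcode was 941 UMIs in the adult and 972 UMIs in the neonatal library, so shallower barcodes had been left out of the deposited counts. All barcodes carried 1 suffix.

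Gene symbols were taken from the files, and 28339 of the 28693 listed features (98.8%) were matched by gene ID to GENCODE M21, from which the coordinates of named genes on mm10 were read. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and leidenalg 0.10.2, and figures were drawn with matplotlib 3.10.9. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library by the share of simulated doublets among each barcode's neighbours, with 2 simulated doublets per barcode, and the highest scores were removed at 0.8% per 1000 barcodes of the library. That removed 149 adult barcodes (3.72%) and 3472 neonatal barcodes (17.0%), which left 3852 and 16947.

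Both libraries were clustered together, without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 20 neighbours was divided by the Leiden algorithm at resolution 1. The fixed lists of cytokines, cell cycle, immediate early, MHC class II and sex-linked genes, and Rora, the YFP feature, mitochondrial and ribosomal genes, were kept out of the clustering genes here and in the repeat within ILC2-like cells. Clusters were named from markers of 22 cell types fixed before the data were examined. A name needed a median marker log2 ratio of at least 0.5 against all other cells and at least 3 markers 1.5-fold or more higher. It was withheld where another class had more markers among the 10 leading genes. A cluster was set aside where the summed CPM of 8 B cell, 7 NK cell or 12 mesenchymal markers reached 25% of the highest cluster of the same library with at least 50 barcodes, outside its own and closely related lineages. Reaching it in 1 library was enough, and that threshold was chosen after the clusters had been seen. Of 28 clusters, 21 were named, 6 were set aside for RNA of another lineage and 1 rested on under 3 markers. Within the ILC2-like cells of each library, clustering was repeated at resolution 0.6.

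Counts were summed per class and library and scaled to UMIs per 1000000 of that sum (CPM), with exact 95% Poisson intervals. Log2 ratios are neonate over adult with 0.5 count added to each sum. Shares of barcodes have exact 95% Clopper-Pearson intervals. With 1 library per group there was no replicate, so no test across samples was made and no p-value is given. Intervals and limits cover counting error only. Library, sequencing depth, sex and pooled animals differ together with age and cannot be separated from it.

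The rule for named genes, fixed before the data were examined, took the 12 genes with the largest log2 ratio in each direction among genes with at least 100 CPM, at least 50 UMIs and a UMI in at least 10% of the cells of the library where they were higher. It left out gene models without an established name, ribosomal, mitochondrial, haemoglobin, immunoglobulin and sex-linked genes, 154 of which passed the size limits, and 1114 genes remained eligible. A named gene at 10-fold or more higher CPM in another class of the same library is given as possibly free RNA. Members of the fixed lists are named beside these whichever way they go. For each of 16 fixed lists, the median log2 ratio of the members with at least 10 UMIs over both sums was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. List members at least 1.5-fold apart were counted. A cell was called cycling at 3 or more UMIs of the cell cycle list after thinning to 1500 UMIs, and shallower cells were left out of that share. Classes with at least 100 cells in both libraries were compared like ILC2-like cells.

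The steps were tested on simulated Poisson counts for the 28693 features, with 200 genes and the cell cycle list changed by known folds. Mean levels came from filtered barcodes with a UMI of Gata3 or Il1rl1, before doublet removal and clustering. Every gene was taken as detected in all cells. The simulation therefore does not cover free RNA, mixed barcodes or the detection limit. All 24 named genes of the simulation, chosen among 1077 eligible genes, were among the changed ones, and 95.0% of the intervals held the true ratio. Genes set at a log2 ratio of 1, -1, 2 and -2 had median estimates of 1.00, -1.02, 1.98 and -1.99, and 41, 43, 48 and 37 of 50 genes in each set lay within 0.25 of the truth. A list set to differ reached percentile 100, and 14 of 14 other lists stayed within the middle 95%. Alternatives covered the cell filters, doublet removal, clustering, scaling, the added count, the low-count filter, cycling cells and the genes in the total, and further ones were added after the data had been seen.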

Results

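Lung cells with low or positive CD45 staining and low staining for lineage markers were profiled by droplet single-cell RNA sequencing, to examine how group 2 innate lymphoid cells (ILC2), tissue lymphocytes that secrete IL-5, IL-13 and amphiregulin, differ among themselves in the neonatal and the adult lung. The mice carried Cre recombinase under the control of Rora, a transcription factor that ILC2 need for their development, and a YFP reporter that stays on once recombined. YFP therefore marks cells with a history of Rora expression. There were 2 libraries, 1 per age, each from pooled lungs. The adult pool was female, with 8 mice of 47 days, 4 of 56 days and 1 of 69 days, and the neonatal pool held mice of both sexes at 12 days. The adult library had 4664 barcodes with 9347580 UMIs in all and a median of 1534 UMIs per barcode. The neonatal library had 21256 barcodes with 42945129 UMIs and a median of 1649. After filtering, 3852 adult barcodes (7593014 UMIs, median 1533.5) and 16947 neonatal barcodes (29997363 UMIs, median 1536) were kept. No replicate libraries were at hand, so each value below describes 1 library, no test was made, and 95% intervals, given in parentheses, cover counting error only. Age differed together with library, sex, pool and sort gate. Levels are given as CPM, UMIs of a gene per 1000000 UMIs summed over the cells of a class in 1 library.

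Sex-linked transcripts were read first, as a check of the labels. In ILC2-like cells Xist, the RNA that silences one X chromosome in female cells, was at 3611 CPM (3495–3729) in the adult and 778 CPM (750.3–806.9) in the neonatal library. Ddx3y and Eif2s3y, both on the Y chromosome, had no UMI in adult ILC2-like cells, which allows up to 3.62 CPM, and stood at 86.9 CPM (77.7–96.8) and 68.3 CPM (60.2–77.2) in neonatal ones. These values match a female adult pool and a neonatal pool of both sexes.

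The first comparison asked which cell classes each library held. ILC2-like cells made up a like share of both, 12.0% of adult barcodes (11.0–13.03; 461 of 3852) and 11.1% of neonatal barcodes (10.6–11.6; 1882 of 16947), and so did NK or ILC1-like cells, at 15.3% (14.2–16.5) and 15.8% (15.3–16.4). The order of the NK or ILC1-like shares depended on the settings. The adult share was the larger with no doublets removed (14.3% adult and 9.37% neonatal) and at resolution 0.5 (15.1% and 11.95%). The neonatal share was the larger at a minimum of 1000 genes (11.1% and 23.97%) and with 1000 variable genes (16.8% and 21.9%). B-like cells took 3.401% (2.85–4.02) of the adult and 10.8% (10.3–11.2) of the neonatal library. Classes with a larger adult share were T-like cells, at 12.6% (11.6–13.7) against 2.64% (2.41–2.90), plasma-like cells, at 11.2% (10.2–12.3) against 0.372% (0.286–0.475), and gamma delta T-like cells, at 4.49% (3.86–5.19) against 0.183% (0.124–0.260). Plasmacytoid dendritic-like cells, specialised producers of type I interferon, took 4.02% (3.43–4.69) and 0.767% (0.641–0.910). Mast or basophil-like cells, at 0.260% (0.125–0.477) and 1.66% (1.48–1.87), and erythroid-like cells, at 0.337% (0.180–0.576) and 1.42% (1.24–1.61), had the larger neonatal share. Adult plasma-like cells held Igha, the heavy chain of IgA, at 4939.6 CPM and Jchain, which joins IgA and IgM units, at 4543 CPM, but also B cell genes near the level of B-like cells, with Cd79a at 3732 CPM against 4705 CPM. The line between these 2 classes depended on the clustering: at resolution 0.5 no plasma-like or gamma delta T-like cluster was named and B-like cells took 14.6% of the adult and 11.2% of the neonatal library, and the adult B-like share was also the larger at minimum gene numbers of 200 (14.4% and 11.1%) and 1000 (5.04% and 2.92%), at most 5% mitochondrial UMIs (11.8% and 10.6%), with no doublets removed (14.2% and 9.40%) and with 1000 variable genes (14.1% and 12.3%).

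Cells outside the blood lineages passed the gate as well. Fibroblast or smooth muscle-like cells were 20.9% (19.6–22.2) of adult and 8.18% (7.77–8.60) of neonatal barcodes, endothelial-like cells 4.54% (3.91–5.25) and 0.366% (0.281–0.469), epithelial-like cells 4.08% (3.47–4.75) and 0.732% (0.609–0.872), and mesothelial-like cells 2.08% (1.65–2.58) and 0.124% (0.0767–0.189). Conventional dendritic-like cells were rare, at 0.0260% (0.000657–0.145) and 0.301% (0.224–0.395). Different clusters held most of 3 classes: NK or ILC1-like cells lay mainly in cluster 12 in the adult (78.5%) and in cluster 3 in the neonate (67.5%), fibroblast or smooth muscle-like cells in clusters 10 (94.3%) and 6 (99.6%), and epithelial-like cells in clusters 23 (77.1%) and 21 (99.2%). No cluster reached the markers of ILC progenitors, such as Zbtb16, the factor that marks committed innate lymphoid precursors, or Tcf7. Such cells would not be seen if too few to form a cluster or if held inside another one, so no share is given and no comparison of ILC progenitor-like cells was made. The sort fixed the ratio of reporter-negative to reporter-positive cells, and only the neonatal gate excluded CD8, which can set the share of T-like cells.

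A large part of the neonatal library could not be given 1 class. Clusters that led with the genes of one lineage and carried RNA of another in the neonatal library were set aside. They held 44.7% (44.0–45.5) of neonatal and 4.67% (4.03–5.39) of adult barcodes. Levels were read only where a library had at least 50 barcodes in the cluster. In the adult only cluster 5 had that many, with NK RNA at 18.4%, under the threshold. Adult barcodes were thus set aside for the neonatal level. The threshold for setting clusters aside was chosen after the clusters had been seen. At 15% in place of 25% of the other lineage's level the shares were 57.0% and 13.2%, and at a minimum of 1000 genes per cell 39.8% and 69.9%. At 15% no plasmacytoid dendritic-like cluster was named, and the neonatal fibroblast or smooth muscle-like share was 0.0354%. Some clusters lay near the threshold. ILC2-leading cluster 5, with 1334 neonatal barcodes, was set aside at 26.6% NK RNA. Neonatal plasmacytoid dendritic-like cells were kept at 23.3% B cell RNA. By their leading markers, 19.9% of neonatal barcodes (19.3–20.5) were set aside from ILC2 and 2.31% (1.86–2.84) of adult ones, 13.3% (12.8–13.9) and 1.06% (0.765–1.44) from NK or ILC1, 8.76% (8.34–9.20) and 0.312% (0.161–0.544) from B cells, and 2.70% (2.46–2.95) and 0.987% (0.699–1.35) from T cells. With the ILC2-leading ones counted in, ILC2-like cells would be 14.3% of the adult and 31.0% of the neonatal library. Without every ILC2-like cell that held a UMI of the B, NK or mesenchymal marker sets, the shares were 9.27% and 4.34%. They were 15.5% and 6.95% with no doublets removed, and 1.68% and 6.20% at a minimum of 1000 genes per cell, so the order of the ILC2-like shares depended on how barcodes were filtered.

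**Figure D1:**
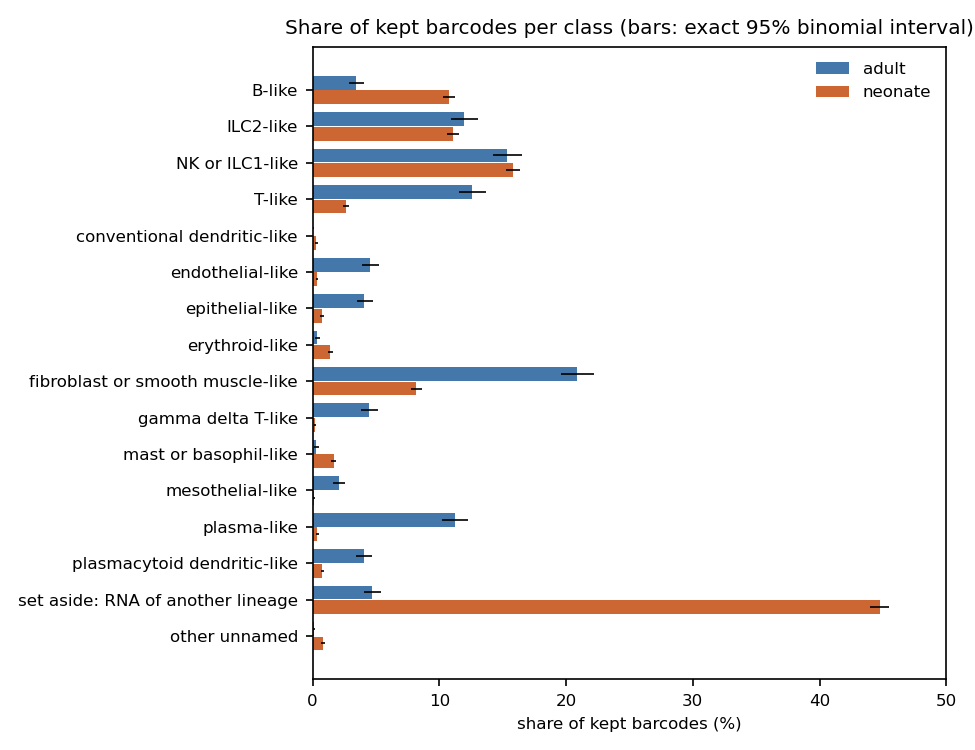
Bars give the share of kept barcodes, in percent, in each class for the adult (3852 barcodes) and neonatal (16947 barcodes) library, with exact 95% binomial intervals. ILC2-like cells took 12.0% and 11.1%, while clusters set aside for RNA of another lineage took 4.67% and 44.7%.

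The central comparison was between adult and neonatal ILC2-like cells, with 461 cells and 1019708 UMIs (median 1605 per cell) in the adult and 1882 cells and 3763776 UMIs (median 1637.5) in the neonate. Adult cells carried more of the chemokine receptor Ccr8, the receptor of Ccl1, at 198 CPM (172–227) against 19.1 CPM (14.97–24.1), a 10.3-fold difference. They also carried more of the interferon-induced gene Ifi27l2a, at 299 CPM (266.5–334.6) against 48.4 CPM (41.6–55.9), the anti-apoptotic gene Bcl2, at 176 CPM (151–203) against 40.4 CPM (34.2–47.3), and Il2, a growth factor for lymphocytes, at 221 CPM (193–251) against 54.2 CPM (47.0–62.2). Neonatal cells carried more of the dividing cell's transcripts Tuba1b, which encodes an alpha tubulin, at 508 CPM (485–531) against 121 CPM (100.2–143.9), and Cenpa, the histone H3 variant of centromeres, at 144 CPM (132–156) against 36.3 CPM (25.5–50.01). Over the 10143 genes measured, the median log2 ratio was -0.04.

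By the fixed rule, 24 genes were named among 1114 eligible ones. Of the 12 higher in adult ILC2-like cells, the rest were Ccdc184 (log2 ratio -2.50), Lpcat2, which makes platelet-activating factor (-2.02), Mdfic (-1.91), Zfp36l2, which speeds the decay of messenger RNAs (-1.87), Tmem176b (-1.85), the GTPase Gimap3 (-1.81), and Scgb1a1 (-7.09) and Gsn (-3.03). Scgb1a1 is the main secreted protein of airway club cells and Gsn encodes the actin-severing protein gelsolin. Both were over 10-fold more abundant in other classes of the adult library, and Scgb1a1 stood near 1675 CPM in NK or ILC1-like and 2106 CPM in T-like adult cells too, so they are given as possibly free RNA. Of the 12 higher in the neonate, Ebf1 (3.13), Ly6d (2.56), Cd79a (2.20) and Cd79b (1.92), all genes of B cells, are given as possibly free RNA in the same way. Cd79a stood at 133 CPM in neonatal ILC2-like, 142 CPM in NK or ILC1-like and 99.3 CPM in T-like cells, against 28.4, 17.4 and 17.8 CPM in the adult library. The others were Fau (4.17), which encodes a ubiquitin-like protein fused to ribosomal protein S30, the glycolytic enzyme Gapdh (2.32), the integrin chain Itgb3 (2.29), Sap18 (1.99), Arf3 (1.86) and the cell cycle kinase subunit Cks1b (1.83). Tuba1b and Cks1b are among the leading genes of cluster 15, a cycling cluster, and Ccdc184 among those of cluster 4, which held 95.2% of adult and 75.3% of neonatal ILC2-like cells. Without cluster 15, Tuba1b had a log2 ratio of 0.48.

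On mm10, Ccr8 (ENSMUSG00000042262) lies on chromosome 9 at 120092114–120094906, Il2 (ENSMUSG00000027720) on chromosome 3 at 37120523–37125959, Bcl2 (ENSMUSG00000057329) on chromosome 1 at 106538178–106714274 and Ifi27l2a (ENSMUSG00000079017) on chromosome 12 at 103442167–103443680. Tuba1b (ENSMUSG00000023004) lies on chromosome 15 at 98931425–98934565, Gapdh (ENSMUSG00000057666) on chromosome 6 at 125161715–125166467 and Fau (ENSMUSG00000038274) on chromosome 19 at 6057844–6059524. All are annotated as protein-coding. The files hold UMI sums per whole gene, so exons and untranslated regions cannot be told apart.

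**Figure D2:**
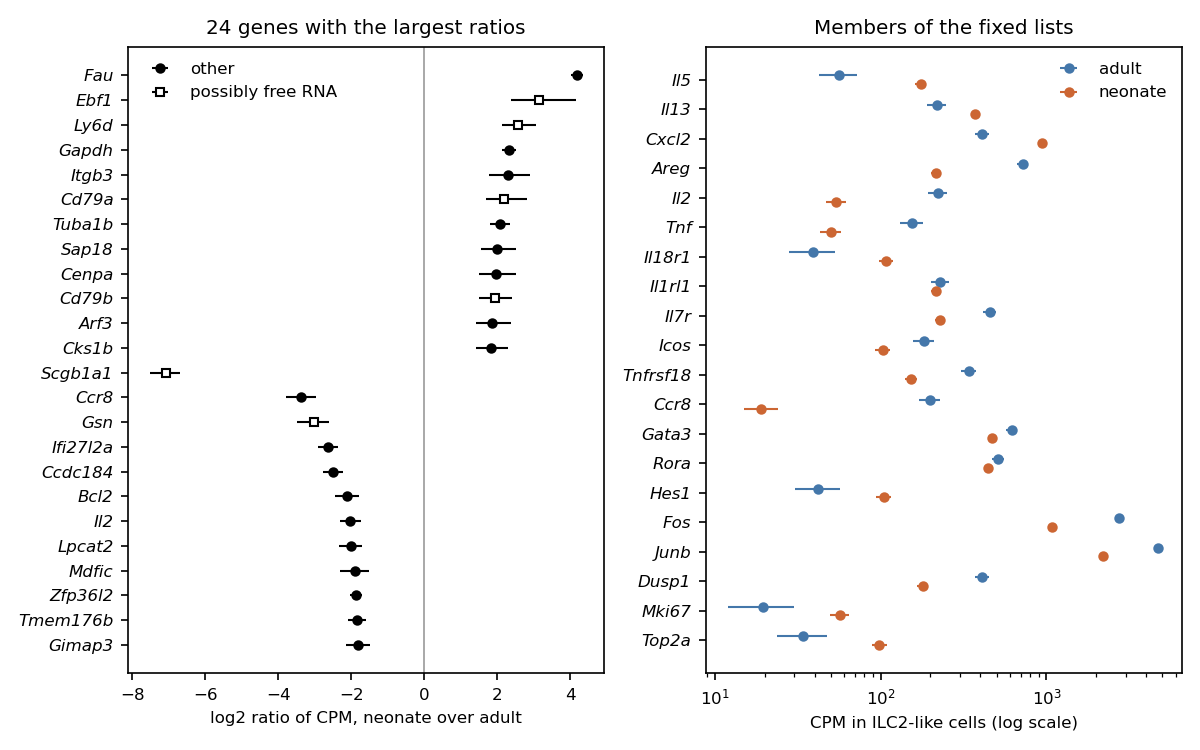
Points on the left give log2 ratios of CPM, neonate over adult, of the 24 named genes in ILC2-like cells, from 4.17 for Fau to -7.09 for Scgb1a1, with 95% intervals for counting error and open squares for possibly free RNA. Points on the right give CPM on a log axis for members of the fixed lists in each library, such as Areg at 720 CPM in the adult and 215 CPM in the neonate.

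Cytokine transcripts of ILC2-like cells went both ways. Areg, which encodes the tissue repair factor amphiregulin, was 3.34-fold higher in the adult, at 720 CPM (669–774) against 215 CPM (201–231). Tnf, at 155 CPM (132–181) against 49.9 CPM (43.1–57.6), and Lif, at 54.9 CPM (41.5–71.3) against 8.77 CPM (6.04–12.3), were higher in the adult too. Il5, whose product drives eosinophil output, was higher in the neonate, at 55.9 CPM (42.3–72.4) in the adult and 175 CPM (162–189) in the neonate, as was Il13, whose product drives mucus secretion, at 219 CPM (191–249) and 372 CPM (353–393), while Il4 differed little, at 43.1 CPM (31.4–57.9) and 46.8 CPM (40.1–54.2). The neutrophil-attracting chemokine Cxcl2 stood at 407 CPM (369–448) and 944 CPM (913–976), and Ccl1, the ligand of Ccr8, at 509 CPM (466–555) and 296 CPM (279–314). Of the 24 measured members of this list, 8 were at least 1.5-fold higher in the neonate and 11 in the adult, and the list's median log2 ratio of -0.12 lay at percentile 17.4 of random lists. It lay outside the middle 95%, toward the adult, in 4 of 20 alternatives, such as -0.47 after thinning to 1500 UMIs. Areg, Il13, Ccl1, Cxcl2 and Il5 are among the leading genes of cluster 4, although cytokine genes were kept out of the clustering.

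Of 20 measured receptors by which ILC2 sense their surroundings, 9 were at least 1.5-fold higher in the adult and 1 in the neonate. Il7r, the receptor for the survival cytokine IL-7, stood at 454 CPM (414–497) and 227 CPM (212–243), and Ramp3, a partner of peptide receptors, at 80.4 CPM (64.0–99.8) and 18.6 CPM (14.5–23.5). Il1rl1, which encodes the IL-33 receptor, differed little, at 228 CPM (200.1–259.8) and 217 CPM (202–232). Il18r1, which encodes the IL-18 receptor, was the 1 higher in the neonate, at 39.2 CPM (28.0–53.4) and 108 CPM (97.6–119). The median of this list, -0.39, lay at percentile 0.410. Among checkpoint and costimulatory receptors, 5 of 14 were higher in the adult and 1 in the neonate (median -0.32, percentile 7.83; -0.71 and 0.260 after thinning to 1500 UMIs), with the costimulatory receptors Tnfrsf18 at 340.3 CPM (305–378) and 152 CPM (140.0–165.2) and Icos at 182 CPM (157–211) and 103 CPM (93.1–114). Klrg1, a lectin-like receptor of mature ILC2, was at 199 CPM (173–228) and 239.9 CPM (224.5–256.1).

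Of 30 transcription factors of innate lymphoid cells, 5 were higher in the neonate and 2 in the adult (median -0.12, percentile 17.3). Gata3, which fixes the ILC2 fate, stood at 618 CPM (571–668) and 470.0 CPM (448–492), Id2, an inhibitor that all innate lymphoid cells need, at 979.7 CPM (919.9–1042.4) and 1164 CPM (1130.0–1199.2), and the Notch target Hes1 at 42.2 CPM (30.5–56.8) and 104 CPM (94.3–115). Genes tied to ILC progenitors had a median of -0.15 (percentile 17.9), with 2 of 18 higher in the neonate and 4 in the adult. Trafficking and residency genes had a median of -0.44 at percentile 0.310, with 7 of 21 higher in the adult, such as Klf2, which keeps lymphocytes in circulation, at 52.0 CPM (38.9–68.0) against 21.5 CPM (17.1–26.7), and Cd69, which keeps them in tissue, at 469 CPM (428–513) against 286 CPM (269.6–304). Sell, the homing receptor L-selectin, at 1.96 CPM (0.238–7.09) and 14.9 CPM (11.2–19.3), and Ccr7, the lymph node homing receptor, at 3.92 CPM (1.07–10.0) and 20.5 CPM (16.1–25.6), were the 2 higher in the neonate. Klf2, Sell and Ccr7 are possibly free RNA by the 10-fold rule, with Klf2 at 642 CPM in adult endothelial-like, Sell at 418 CPM in neonatal plasmacytoid dendritic-like and Ccr7 at 1655 CPM in neonatal conventional dendritic-like cells.

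Most stress and interferon genes measured at least 1.5-fold apart were higher in adult ILC2-like cells. Of 21 immediate early and dissociation stress genes, 14 were at least 1.5-fold higher in the adult and only Ier3 in the neonate, with a median of -0.995 at percentile 0 of 10000 random lists. Fos, an early response transcription factor, stood at 2719 CPM (2619–2823) and 1083 CPM (1050.0–1116.7), its partner Junb at 4723 CPM (4590.5–4858.2) and 2187 CPM (2140.2–2234.9), and the heat shock gene Hspa1a at 54.9 CPM (41.5–71.3) and 13.02 CPM (9.63–17.2). Hspa8, the most abundant heat shock gene of the list, went the other way, at 1464 CPM (1391–1540.3) and 1972 CPM (1927–2017), and Dnaja1 differed little, at 306 CPM (273–342) and 307 CPM (289.7–325.4). Hspa1a, at 972 CPM in adult endothelial-like cells, and Ier3, at 1424 CPM in neonatal mast or basophil-like cells, are possibly free RNA by the same rule. Of 13 type I interferon response genes, 7 were higher in the adult and 0 in the neonate (median -0.60, percentile 0.520), among them the ubiquitin-like Isg15 at 45.1 CPM (33.0–60.2) and 14.3 CPM (10.8–18.7). The interferon difference was uneven among adult cells: these genes summed to 283 CPM (234–338) in adult sub-cluster 0, described below, 1252 CPM (1119–1396) in sub-cluster 1, which also carried RNA abundant in other classes, and 504 CPM (430.4–585.9) in sub-cluster 2, against 243, 259 and 268 CPM in the neonatal sub-clusters. The interferon list came inside the middle 95% without cycling cells (percentile 5.43), without the cycling cluster (9.83) and without cells holding B, NK or mesenchymal UMIs (3.97), and the trafficking list without cycling cells (2.965), without the cycling cluster (3.68), after thinning to 1500 UMIs (2.94) and at resolution 0.5 (4.965).

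Cell cycle genes were, apart from the sex-linked check, the list furthest toward the neonate. All 34 members were measured, 30 were at least 1.5-fold higher in the neonate and 0 in the adult, and the median of 1.503 lay at percentile 100. The size of this median depended on the setting, at 0.60 without cycling cells and 0.96 with a prior of 5 counts. Mki67, a marker of dividing cells, stood at 19.6 CPM (12.0–30.3) and 56.9 CPM (49.5–65.0), Top2a, which untangles replicated DNA, at 34.3 CPM (23.9–47.7) and 98.6 CPM (88.8–109), and Birc5, the mitotic regulator survivin, at 43.1 CPM (31.4–57.9) and 135 CPM (123–147). Imprinted growth and fetal genes lay inside the middle 95% (median -0.69, percentile 2.565, 8 of 17 measured), with a median of 0.25 without cells holding B, NK or mesenchymal UMIs and -0.13 after thinning to 1500 UMIs. Of the 8, 5 were higher in the adult, such as the noncoding RNA Meg3 at 11.8 CPM (6.08–20.6) and 3.99 CPM (2.23–6.57), and 2 in the neonate, such as Igf2bp3, a fetal RNA-binding protein, at 1.96 CPM (0.238–7.09) and 16.5 CPM (12.6–21.1). Medians of the other lists were -0.10 for MHC class II (percentile 36.7), -0.07 for lipid use (48.3), -0.11 for cholesterol synthesis (46.2), 0.19 for glycolysis (92.3) and -0.10 for NF-kB (31.0). The sex-linked list, whose members follow the sex of the pools, had a median of 4.68.

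Beside the sex-linked list, 5 of 15 lists lay outside the middle 95% of random lists: cell cycle, immediate early, receptors, interferon and trafficking. With each library clustered alone only cell cycle and immediate early genes stayed outside, MHC class II joined them at a median of 0.79, and receptors (percentile 3.43), interferon (28.7) and trafficking (13.9) came inside. Only 13 adult cells were left at a minimum of 1000 genes per cell, where the immediate early median was 0.11, the receptor median 0.53 and the cell cycle median -0.70.

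**Figure D3:**
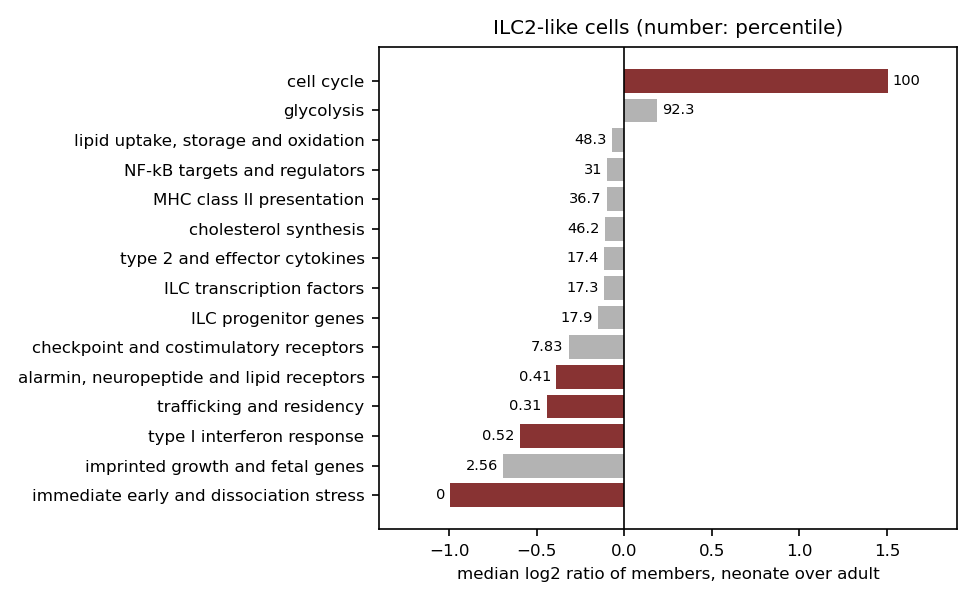
Bars give the median log2 ratio, neonate over adult, of the measured members of each of 15 fixed lists in ILC2-like cells, and the number beside each bar is its percentile among 10000 random lists. Dark red bars mark the 5 lists outside the middle 95%, from -0.995 for immediate early genes to 1.503 for cell cycle genes.

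Cycling cells were counted after thinning every cell to 1500 UMIs. Among ILC2-like cells, 6.20% of adult (3.59–9.88; 16 of 258) and 28.5% of neonatal cells (25.8–31.3; 306 of 1073) held at least 3 UMIs of cell cycle genes, with 203 adult and 809 neonatal cells too shallow to count. Unthinned, the shares were 6.94% and 23.4%. NK or ILC1-like cells showed the same order, at 12.1% (8.05–17.2) and 36.9% (34.4–39.4), as did fibroblast or smooth muscle-like cells, at 0.427% (0.0518–1.54) and 4.60% (3.15–6.47), while T-like cells stood at 10.9% (7.16–15.6) and 15.4% (11.0–20.7). In B-like cells, which gave the background, the share was 3.70% (0.0937–18.97; 1 of 27) and 1.87% (0.812–3.66; 8 of 427), at median depths of 1141 and 1238 UMIs. The 2 ILC2-like shares depended on which clusters made up the class: they were 0.617% and 2.70% with no doublets removed, 0.554% and 3.27% at clustering resolution 0.5, and 0.971% and 2.79% with each library clustered alone.

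Heterogeneity within ILC2-like cells was then read in each library alone, with cytokine, cell cycle, immediate early and MHC class II genes and Rora kept out of the clustering. Each library gave 3 sub-clusters, which are numbered and left unnamed. In the adult, sub-cluster 0 (272 cells, 59.0%) held most of the transcripts of Il5, at 100.4 CPM (72.7–135), against 15.5 CPM (4.22–39.7) in sub-cluster 1 (106 cells, 23.0%) and 29.98 CPM (14.4–55.1) in sub-cluster 2 (83 cells, 18.0%). Il2 followed the same order between the first pair, at 355 CPM (301–416) and 23.3 CPM (8.54–50.6), as did Ccl1, at 803 CPM (721–893) and 11.6 CPM (2.40–34.0). Il13 was spread differently, at 217 CPM (175–266), 337 CPM (270.1–416.0) and 129 CPM (93.3–174), and Areg was present in all, at 827 CPM (743–917), 558 CPM (471–657) and 708 CPM (620.2–803.9).

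Adult sub-cluster 1 stood apart from the other adult sub-clusters in several lists. Its immediate early genes summed to 8606 CPM (8251–8971) against 18876 CPM (18467–19292) in sub-cluster 0 and 19842 CPM (19367–20326) in sub-cluster 2, its interferon genes to 1252 CPM against 283 and 504 CPM, and its MHC class II genes to 2609 CPM (2415–2814) against 283 and 273 CPM. Cd74, the invariant chain of MHC class II, alone stood at 1585 CPM (1436–1747) there, and 23.4% of its 77 cells deep enough to count were cycling, against 0 of 108 and 0 of 73. The same sub-cluster also held most of the immunoglobulin light chain Igkc, at 837 CPM (729–957), and of Gzma, the granzyme of cytotoxic cells, at 671 CPM (574–778), both of which are abundant in other classes. The receptor list summed to 1136 CPM (1009–1274) in sub-cluster 1, against 2524 and 2851 CPM in sub-clusters 0 and 2. Over the adult sub-clusters, Il1rl1 ranged from 46.5 to 306 CPM and Klrg1 from 117 to 419 CPM. The median depth of the adult sub-clusters was 1373.5, 2074.5 and 3722 UMIs, so they differ in depth as well.

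In the neonate, 1 sub-cluster stood apart by its dividing cells and by its depth, with a median of 2579 UMIs against 1564 and 1407. Sub-cluster 2 (446 cells, 23.7%) held 3503 CPM (3400.3–3607.5) of cell cycle genes against 331 CPM (302–362) in sub-cluster 0 (771 cells, 41.0%) and 362 CPM (326–399.6) in sub-cluster 1 (665 cells, 35.3%), and 75.1% of its 377 countable cells were cycling against 4.59% of 414 and 4.96% of 282. It had less Il5, at 96.6 CPM (80.3–115) against 203 CPM (180.0–227.2) and 230.1 CPM (202–261), and less Areg, at 137 CPM (117–159) against 272 CPM (246–301) and 231 CPM (203–262). Sub-cluster 1, which led with Actn2, Lgals3 and Klrg1, had the most Il13, at 598 CPM (553–647) against 322 CPM (293–352) in sub-cluster 0 and 240.0 CPM (214–269) in sub-cluster 2. Areg was below the lowest adult sub-cluster in every neonatal one. Igkc stood at 1393 CPM (1329–1460.0) in sub-cluster 2 against 326 and 304 CPM. At resolution 1.0 the neonatal cells gave 6 sub-clusters and the adult cells 4.

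**Figure D4:**
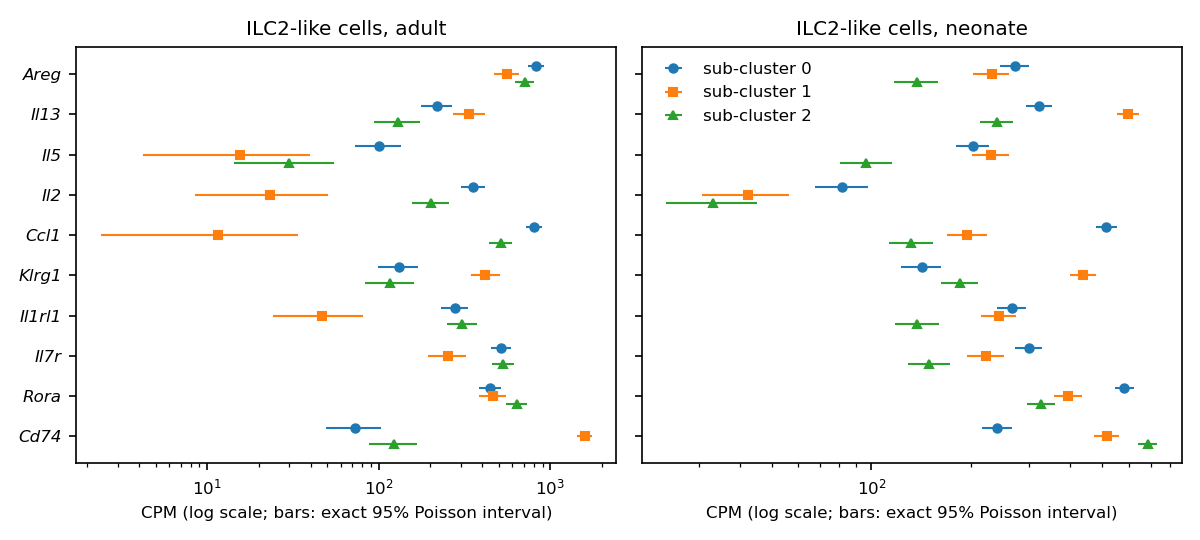
Points give CPM on a log axis of 10 genes in the 3 sub-clusters of ILC2-like cells in the adult (left) and the neonatal library (right), with exact 95% Poisson intervals. Areg lies at 558 to 827 CPM in the adult and at 137 to 272 CPM in the neonatal sub-clusters.

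Rora, kept out of clustering and naming, was most abundant in ILC2-like cells of both libraries, at 512 CPM (469–558) in the adult and 444 CPM (423–466) in the neonate. Gamma delta T-like cells came next, at 417 CPM (348–496) and 412 CPM (252–637), the latter from 31 cells, followed in the adult by T-like cells at 203 CPM (173–235). NK or ILC1-like cells held 64.1 CPM (48.8–82.7) in the adult and 146 CPM (136–157) in the neonate, and fibroblast or smooth muscle-like cells 139 CPM (120.4–158.6) and 207 CPM (189–227), with different clusters holding each of these classes at the 2 ages. B-like and plasma-like cells held the least, with 0 CPM (0–22.3) and 12.9 CPM (5.91–24.6) in the adult and 32.0 CPM (25.3–39.9) and 33.3 CPM (6.87–97.3) in the neonate. Neonatal erythroid-like cells held 206 CPM (169–249) of Rora, and also Cd79a at 753 CPM and Gzma at 881 CPM. Mast or basophil-like cells held 178 CPM (144–218) in the neonate. The neonatal NK or ILC1-like and fibroblast or smooth muscle-like values are therefore not shown to lie above RNA of other cells.

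The YFP feature, chosen for report after the gene list had been seen, reads the tracer itself. Its transcripts stood at 627 CPM (579–677) in adult and 723 CPM (696–750.4) in neonatal ILC2-like cells, and at 36.3 CPM (13.3–79.1) and 45.5 CPM (37.5–54.8) in B-like cells. NK or ILC1-like cells, in which Rora itself was low in the adult, held 419 CPM (378–463) and 432 CPM (413–450.4) of YFP. Fibroblast or smooth muscle-like cells held 806 CPM (761–853) and 665 CPM (633–699.5). Neonatal erythroid-like cells, which also carried Cd79a and Gzma, held 328 CPM (281–381) of YFP. The sort fixed the ratio of reporter-negative to reporter-positive cells, so these levels do not give shares of marked cells in the lung.

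**Figure D5:**
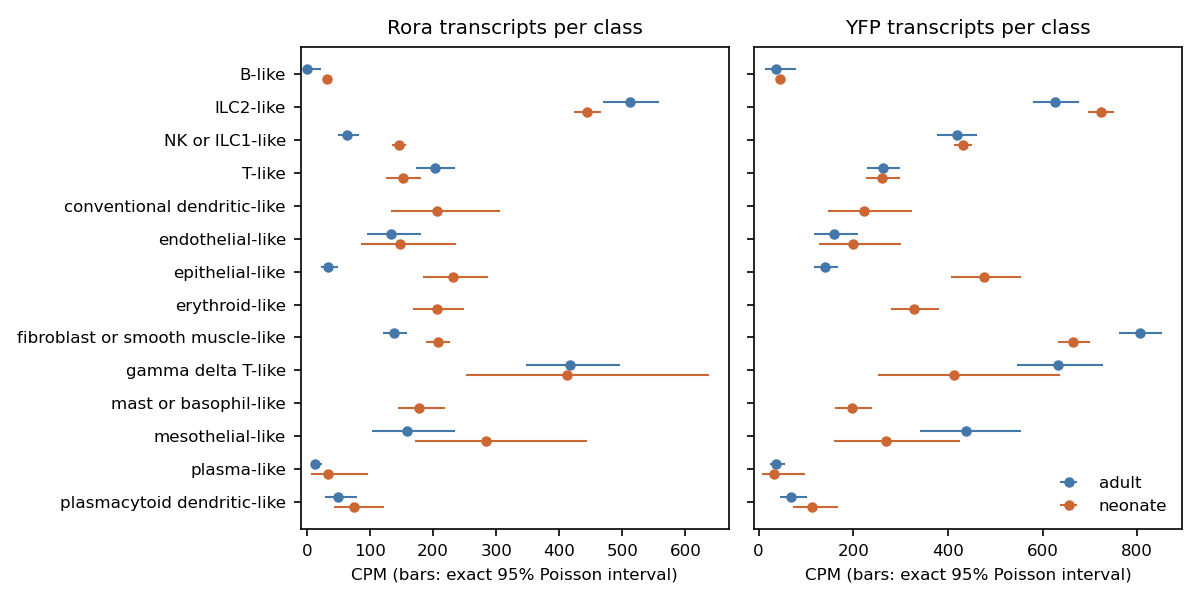
Points give CPM of Rora (left) and of the YFP reporter (right) per class and library, with exact 95% Poisson intervals. ILC2-like cells had the most Rora, at 512 and 444 CPM, and fibroblast or smooth muscle-like cells the most YFP in the adult, at 806 CPM.

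To see which differences were not particular to ILC2-like cells, the 24 named genes were read in the 6 other classes with at least 100 cells in both libraries. Different clusters held most NK or ILC1-like, fibroblast or smooth muscle-like and epithelial-like cells in each library, so these classes may compare unlike cells. Fau, Gapdh, Itgb3, Sap18, Arf3, Scgb1a1 and Gsn differed at least 2-fold the same way in all 6, while Bcl2, Tmem176b and Gimap3 did so in none. The number of the 24 that did was 14 in B-like, 13 in NK or ILC1-like, 15 in T-like, 15 in plasmacytoid dendritic-like, 18 in fibroblast or smooth muscle-like and 16 in epithelial-like cells. Scgb1a1 alone took 576037 CPM of adult epithelial-like cells, which lowers every other gene there, and with size factors that count was 11. Immediate early genes had a median of 1.31 there. Elsewhere, these genes had medians of -0.47 in B-like, -0.67 in NK or ILC1-like, -0.84 in T-like, -1.01 in plasmacytoid dendritic-like and -1.23 in fibroblast or smooth muscle-like cells, and interferon response genes of -0.62, -0.43, -0.80, -0.91 and -1.76. Cell cycle genes had medians of 1.35 in NK or ILC1-like, 0.46 in T-like and 1.51 in fibroblast or smooth muscle-like cells. Ccr8 stood at 14.2 CPM in adult and 5.03 CPM in neonatal T-like cells and Areg at 67.6 and 22.6 CPM, both below their level in ILC2-like cells. Areg was also higher in the adult in fibroblast or smooth muscle-like (135 and 36.6 CPM) and plasmacytoid dendritic-like cells (44.4 and 14.1 CPM), and lower in the adult in NK or ILC1-like (3.26 and 15.7 CPM) and epithelial-like cells (38.6 and 147 CPM). Il13 and Cxcl2 had log2 ratios toward the neonate in all 6 other classes, and Il5 in all but B-like cells. Some intervals of these ratios held 0. Neonatal levels in the 6 classes were below those of ILC2-like cells. They were 11.1 to 141 CPM against 372 for Il13, 4.48 to 84.5 CPM against 175 for Il5, and 42.2 to 352 CPM against 944 for Cxcl2. RNA from other cells was not excluded as their source.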

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

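The tests of haemoglobin RNA and of median UMI counts were chosen after their results had been seen, and the other tests below were set before. The differences between classes were not tested, and age stays an untested biological explanation for each.

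Several genes higher in adult ILC2-like cells had a log2 ratio of the other sign in another class, on few UMIs. Bcl2, at -2.12 in ILC2-like cells, stood at 1.94 (0.93 to 3.04) in epithelial-like and 2.64 (-0.08 to 8.65) in plasmacytoid dendritic-like cells. Gimap3, at -1.81, stood at 1.84 (-0.10 to 7.74) in B-like, 2.28 (1.21 to 3.50) in epithelial-like and 1.84 (0.09 to 4.08) in plasmacytoid dendritic-like cells. Tmem176b, at -1.85, stood at 2.00 in B-like cells, on 0 adult and 29 neonatal UMIs, with a lower limit of -1.002, and Il2, at -2.03, at 1.08 (-0.37 to 3.62) in NK or ILC1-like and 1.86 (0.24 to 3.67) in epithelial-like cells. Where an interval holds 0 the direction in that class is not settled. Ccdc184 (-2.50), Mdfic (-1.91) and Zfp36l2 (-1.87) stood at 1.56, 1.86 and 2.30 in epithelial-like cells. The median of all protein-coding genes in epithelial-like cells was 1.58. The epithelial-like intervals of Bcl2, Gimap3 and Il2 hold that value, so their direction beyond this shift is not settled either.

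Clusters outside the named classes held 44.7% of neonatal barcodes where RNA of another lineage was present, and 0.820% (0.690–0.968) in cluster 22, which led with Car1, Myb and Igha. They are given here because no comparison under the main settings used these barcodes, while an alternative kept the ILC2-leading ones.

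Of the set-aside neonatal barcodes, 2260 led with NK genes and carried B cell RNA. Their B cell markers, by which they were set aside, summed to 4996 CPM against 602 CPM in NK or ILC1-like cells, while haemoglobin RNA, which the rule for setting barcodes aside did not use, stood at 421 CPM (400.2–442.7) and 355 CPM (338–372), a ratio of 1.19 (1.11–1.27), which argues against a larger amount of free RNA of the library's common composition. Their median of 1423.5 UMIs was 0.901 times (0.877–0.928) that of NK or ILC1-like cells. The 3472 neonatal barcodes scored most like doublets had been removed before. This ratio therefore cannot decide on 2 cells, each as deep as those of its class, under 1 barcode. Xist and a Y-linked transcript stood together in 4.57% (4.11–5.07) of all set-aside and 2.54% (2.098–3.04) of NK-like and ILC2-like barcodes, a ratio of 1.80, past the bound of 1.5 set against 1 cell with both programmes, and in 5.05% (4.17–6.05) of NK-leading ones, near the 5.49% (4.58–6.51) of simulated mixtures of an NK-like and a B-like barcode, but B-like barcodes alone held both in 5.66% (4.60–6.88), so that bound was wrong and the test does not separate RNA of several cells from 1 cell. Several cells under 1 barcode, whole, shallow or broken, 1 cell with both programmes, and age stay open.

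Fau, Gapdh and several ribosomal genes were higher in the neonate in all 7 classes compared, Fau by a log2 ratio of 4.17 in ILC2-like and 4.61 in B-like cells. Processed pseudogenes, many of them copies of such genes, had a median log2 ratio of -1.61 in ILC2-like cells, where 44 of 52 were at least 1.5-fold lower in the neonate, while protein-coding genes had -0.03. The pseudogene median lay at -1.64 in B-like, -1.39 in NK or ILC1-like and -1.26 in plasmacytoid dendritic-like cells. In epithelial-like cells, whose adult sums Scgb1a1 fills, it was 0.18, against 1.58 for protein-coding genes. Pseudogenes thus lay below protein-coding genes in all 7 classes. Reads counted for pseudogenes in one library and for their parent genes in the other stay open. They cannot be told apart from an effect of age because each age had 1 library. A different annotation or version of the counting between libraries was not tested.

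Areg and immediate early genes were higher together in adult ILC2-like cells. In 5 sets of cells matched on their immediate early share, Areg was still 3.13-fold (2.77–3.50) higher in the adult, which argues against the immediate early level of the cells alone for Areg. The immediate early median lay at -0.47 in B-like, -0.67 in NK or ILC1-like, -0.84 in T-like and -1.01 in plasmacytoid dendritic-like cells, and the highest of these missed the bound of -0.5 set for a dissociation response of the whole adult library. Such a response cannot be told apart from age for the immediate early genes, because 3 of 4 classes passed that bound. An age difference of Areg itself stays open and untested.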

How the results depend on the processing

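The alternatives that changed the treatment of clusters carrying other RNA, removed cells with marker UMIs or the cycling cluster, or used another seed were added after the data had been seen. With 1 library per age and medians of 1605 and 1637.5 UMIs per ILC2-like cell, genes at low levels are measured only as class sums, and no alternative can separate age from library. No paired analysis was possible because there is 1 library per group and no test. Each barcode suffix alone was not run, since all barcodes carry 1 suffix, and no alternative gave ILC progenitor-like cells, so none has values for that comparison. Of the 24 named genes, 16 (at least 1000 genes) to 24 stayed 2-fold or more apart the same way over 20 alternatives. Log2 ratios of 45 genes were followed, the 24 named ones and chosen list members and markers. Other genes given above, such as Il4, Lif, Ccl1 and Mki67, were not. Over the alternatives set beforehand, 540 of 674 values stayed within the interval of the reported value, 118 left it with the same sign and 16 with the other sign. Over added ones 187 of 221 stayed. Sign changes within the interval included, 27 and 4 values had the other sign, mostly of Il1rl1, Zbtb16 and Tcf7. Of list medians, 186 of 225 and 65 of 75 stayed, and 15 and 5 had the other sign. Cell cycle genes lay outside the middle 95% of random lists in 20 of 20 alternatives, on the low side in 1 of them, immediate early genes in 19, receptors in 18, on the high side in 1, interferon genes in 16 and trafficking genes in 15. Cytokines lay outside in 4, all on the low side: -0.61 at a minimum of 200 genes, -0.47 after thinning to 1500 UMIs, -0.29 at resolution 2.0 and -0.55 without cells holding B, NK or mesenchymal UMIs. Checkpoint receptors lay outside in 2, at -0.71 after thinning and -0.48 with ILC2-leading clusters kept, and imprinted genes in 2, at -0.76 at resolution 2.0 and -0.91 without the cycling cluster. MHC class II lay outside in 4, on the low side in 2 and on the high side in 2, and cholesterol synthesis in 1, at percentile 1.81. Areg kept its sign throughout, at log2 ratios from -1.96 to -0.87, while Tuba1b, at 2.07, came down to 0.36 with each library clustered alone. A prior of 5 counts moved the median of all genes from -0.04 to -0.31. The cause was not tested for any value below, where the 2 percentages are adult and neonate.

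At least 1000 genes left 13 adult and 272 neonatal ILC2-like cells, with shares of 1.68% and 6.20%, cycling shares of 84.6% and 75%, and log2 ratios of -0.34 for Cks1b, 0.23 for Bcl2, 1.67 for Lpcat2, 0.0862 for Mdfic, 0.48 for Cd69, 0.79 for Isg15, 0.79 for Tnf, 1.22 for Gata3, 0.21 for Rora and 1.42 for Il1rl1. List medians there were 0.16 for cytokines, 0.53 for receptors, 0.21 for transcription factors, -0.70 for cell cycle, 0.11 for immediate early, -1.92 for MHC class II, -1.39 for interferon and 0.23 for imprinted genes. At least 200 genes gave a neonatal share of 12.4%. At most 5% mitochondrial UMIs gave shares of 16.8% and 10.2%, Il1rl1 at 0.21 and Zbtb16 at -1.45. With no doublets removed, shares were 15.5% and 6.95%, cycling shares 0.617% and 2.70%, Rora 0.0419, Il1rl1 0.36 and the checkpoint median 0.12. Resolution 0.5 gave shares of 17.2% and 15.9%, cycling shares of 0.554% and 3.27%, and Il1rl1 at 0.15. With 1000 variable genes and 20 components, the neonatal cycling share was 19.04%, Il1rl1 0.26, the cytokine median 0.10, the checkpoint median 0.0785 and the MHC class II median -0.57. Each library clustered alone gave shares of 9.61% and 8.32%, and cycling shares of 0.971% and 2.79%, and lists outside the middle 95% were 3 against 5, namely cell cycle, immediate early and, outside the 5, MHC class II at 0.79. Without cycling cells that median was 0.40. Thinning to 1000 UMIs with at least 2 UMIs gave a neonatal cycling share of 21.1%. Resolution 1.0 within ILC2-like cells gave 6 neonatal sub-clusters against 3.

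With clusters that lead with ILC2 markers kept in the class, shares were 14.3% and 31.0%, the neonatal cycling share 11.6%, Klrg1 -0.0550, the MHC class II median 0.28 and the glycolysis median -0.0397. Without cells holding B, NK or mesenchymal UMIs, shares were 9.27% and 4.34%, the neonatal cycling share 21.01% and the imprinted median 0.25. Without the cycling cluster, the neonatal share was 8.37%, cycling shares 0% and 2.496%, the cytokine median 0.0517 and the MHC class II median 0.18.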

Other observations

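The genes and classes in this part were picked for mention after their values had been seen, and no test was made. T-like cells lay in a single cluster in both libraries. Interferon response genes were higher in the adult there as well, with 8 of 13 at least 1.5-fold higher in the adult and 0 in the neonate (median -0.80, percentile 0.0100). Ifi27l2a stood at 1787 CPM (1698–1880.0) in adult and 495 CPM (447–546) in neonatal T-like cells, Bst2, which tethers virus particles to the cell, at 116 CPM (94.3–142) and 51.5 CPM (37.0–69.9), and Isg15 at 64.0 CPM (48.1–83.5) and 23.9 CPM (14.4–37.3). Checkpoint and costimulatory receptors had a median of -0.60 (percentile 0.0800), with 7 of 13 higher in the adult, among them Ctla4, an inhibitory receptor, at 191 CPM (162–223) and 79.2 CPM (60.8–101). Trafficking genes had a median of -0.38, with 8 of 21 higher in the adult, such as Klf2 at 145 CPM (120.1–172.7) and 67.9 CPM (51.0–88.5). Cd4 was higher in adult T-like cells, at 48.6 CPM (34.9–65.9) and 8.80 CPM (3.54–18.1), while Cd8b1 differed little, at 251 CPM (219–287) and 227 CPM (196–263), although only the neonatal gate excluded CD8. A further T-leading cluster, led by Cd8b1, had been set aside for B cell RNA, with 457 neonatal and 38 adult barcodes. None of these T-like values includes it, so they depend on that removal.

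In plasmacytoid dendritic-like cells, MHC class II genes had a median of -0.89 (percentile 0.0800), with 5 of 9 higher in the adult and 1 in the neonate, and cholesterol synthesis genes a median of -0.61 (percentile 0.475), with 7 of 13 higher in the adult and 0 in the neonate. This cluster carried B cell RNA at 23.3% of the B-like level in the neonate and 5.04% in the adult. Cd79a was found in 53.1% and 14.2% of its cells. The effect of such RNA on these medians was not tested. Gamma delta T-like cells held Il17a, the gene of a cytokine that draws neutrophils, at 153 CPM (113–204) in the adult and 20.6 CPM (0.522–115) in the neonate, the latter from 1 UMI in 31 cells.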
